A study of Mus musculus with 8 samples.

How the data were processed

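Total RNA was taken from flash-frozen brown adipose tissue of 8 mice and depleted of ribosomal RNA with a Ribo-Zero Gold kit, per the labels' protocols. Reads were aligned with STAR 2.0.4b and assigned to genes with featureCounts 1.45 of the Subread package on GRCm38, per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of overlapping, antisense or near-identical genes can therefore not be told apart.

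The authors deposited 1 table per library with 41388 Ensembl genes, their coordinates and lengths, and 3 values per gene. Per the file headers, the deposited values are a whole-number read count, a CPM and an RPKM. The deposited CPM equals the count divided by the sum of the counts of that table and scaled to 1e+06. The deposited RPKM equals that CPM divided by the gene length in kb, both checked to within 1e-09. Only the counts entered the tests. CPM values printed here were recomputed from the counts with scaled library sizes, unless stated to be before scaling.

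Gene symbols and types were taken from GENCODE M21 (GRCm38) by Ensembl gene ID, which matched 40340 of the 41388 genes. Of these, 40244 overlapped the coordinates in the files. The 355 rRNA rows were left out of library sizes and tests. They held 2.83% to 3.53% of the counts in WT and 0.801% to 1.13% in ANKO. Total counts ran from 5738067 to 49697156 per library. Depth limits low genes most in ANKO4, where 3 counts are 0.523 CPM. PCR copies are not independent molecules, so such floors cover counting error only.

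Samples were grouped by their titles and genotype labels into 4 WT and 4 ANKO mice. The series design names 4 control and 4 ANKO mice, so the replicates are animals. No 2 libraries agreed within sampling noise: the lowest chi-square per degree of freedom between libraries was 7.16 (ANKO1 and ANKO2). The main comparison used edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, library sizes were scaled by TMM, and the quasi-likelihood test was fitted with robust dispersion and no covariate. P-values were adjusted by Benjamini-Hochberg over the 16705 genes tested, and an adjusted p under 0.05 was called. The biological coefficient of variation was 20.6%. Standard errors of log2 fold changes were derived from the F statistic. Differences of Nampt were also tested with an exact permutation test of log2 CPM.

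Before the data were examined, 38 gene lists were fixed, 9 of them markers of cell types that a brown fat dissection can hold. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. With the preset correlation 26 lists were called, 12 higher and 14 lower, and with the estimated correlation 0 were called. Member counts adjusted over the list alone differed from those over all genes in 9 lists and were equal in 29.

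The genes named in the text follow a rule fixed in advance. It takes Nampt, 11 fixed genes, and in each direction the 8 protein-coding genes with the largest change among called genes with a mean of at least 2 CPM, non-overlapping groups and no predicted name. From each list it takes up to 2 called members with the smallest p in the direction of the list. A gene that this rule takes is not reported here. List members outside the rule, named as exceptions to their list, were chosen after their values were seen. So were the genes and lists introduced as such in the closing section.

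The alternatives fixed in advance were other scaling factors, other filters on low counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, protein-coding nuclear genes alone, the muscle marker level as a covariate, stricter thresholds, and the other set tests. Thinning to the lowest library total and leaving out pairs of WT libraries were added after the data had been seen. The gene and list tests were tested on simulated data with the means and library sizes of the 8 libraries over 16705 genes. The gene test recovered 13.4% of genes changed 1.5-fold, 58.2% of those changed 2-fold and 89.4% of those changed 4-fold, with 6 false calls (5.22% of calls). The simulation left 16485 genes unchanged, far more than in the data, so its adjusted p set a stricter cutoff. Its recovery rates are therefore not those of the real comparison. Genes were drawn independently, so the list test was not tried on correlated members. Figures were drawn with matplotlib 3.10.9.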

Results

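Gene expression was measured by sequencing of rRNA-depleted total RNA from the brown adipose tissue of 8 mice, labelled C57BL/6J and kept at room temperature on regular chow. In 4 mice (ANKO) a Cre recombinase driven by the adiponectin promoter, which is active in adipocytes, was combined with floxed alleles of Nampt. The other 4 mice (WT) carried the floxed alleles and were labelled wild type. The comparison asks which transcripts of brown fat differ when adipocytes lack Nampt, the enzyme that makes nicotinamide mononucleotide from nicotinamide in the NAD+ salvage pathway. The WT libraries held 21771276, 27404629, 37309875 and 49697156 gene counts. The ANKO libraries held 26426476, 8700629, 10107921 and 5738067, so the median WT total was 3.44 times the median ANKO total. A level of 3 counts corresponded to 0.0604 CPM in the deepest library and to 0.523 CPM in the shallowest, counting error only. Xist was read in all 8 libraries, at 1029 to 1642 CPM before scaling. Ddx3y, Eif2s3y and Kdm5d had 0 counts in each library, and Uty had 1 count in WT4 and 1 in ANKO1.

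Nampt (ENSMUSG00000020572, chromosome 12, 32820335 to 32853369, plus strand, GRCm38) was lower in every ANKO library than in every WT library. Its mean was 508 ± 42.2 CPM in WT and 72.3 ± 4.67 CPM in ANKO (SD, n = 4 each), which left 14.2% of the WT level. The log2 fold change was -2.81 with a standard error of 0.12 (edgeR adjusted p = 1.51e-07). An exact two-sided permutation test gave p = 0.0286, the smallest p that 4 against 4 libraries allow. The gene count keeps reads from undeleted exons and from cells without Cre. Gdap10, a non-coding gene whose span (32821872 to 32826904) lies inside that of Nampt, also fell, by 1.68 on the log2 scale, and reads of the overlapping genes may not be told apart by the counting. Of 13 other tested genes within 1 Mb of Nampt, 4 were higher and 3 lower.

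**Figure D1:**
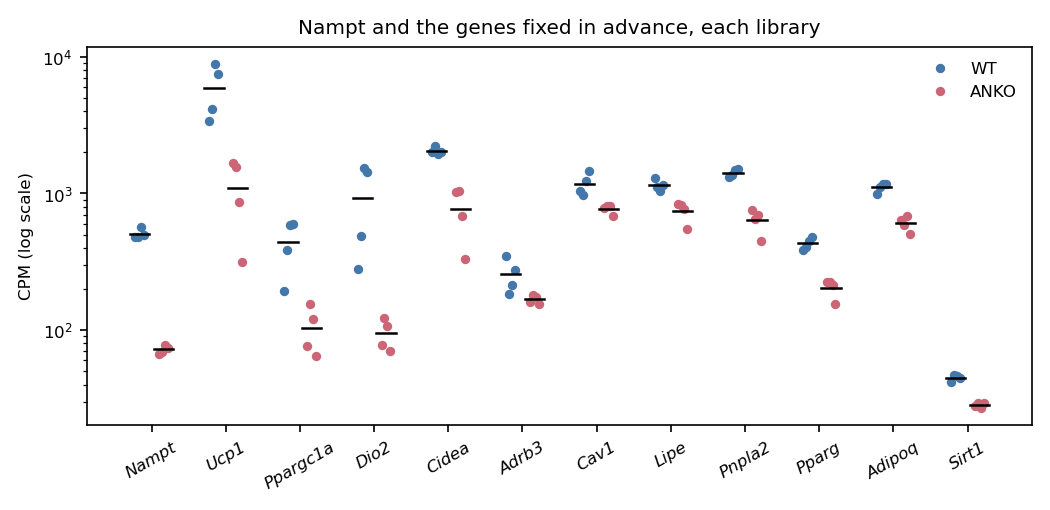
Scaled CPM (log axis) of Nampt and of the 11 genes fixed before the data were examined. Points are single libraries (WT blue, ANKO red) and bars are group means of 4. Nampt lies near 508 CPM in WT and near 72.3 CPM in ANKO, and Ucp1 at 317 to 1673 CPM in ANKO against 3369 to 8829 CPM in WT.

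Brown fat of ANKO mice had lower transcript levels of thermogenic, mitochondrial and adipocyte genes and higher levels of immune, interferon-response, matrix and proliferation genes than WT brown fat. Of 16705 genes tested, 9726 differed (58.2%, edgeR adjusted p under 0.05), with 5111 higher and 4615 lower in ANKO. A change of at least 1 on the log2 scale was seen for 4786 of them, 3577 higher and 1209 lower. Among called genes with a mean WT level of 100 CPM or more, 1253 were lower and 133 higher. This cut uses the WT level alone, so it leaves out genes abundant only in ANKO and leans towards falls. Falls in lists of genes abundant in WT are part of a wider fall of such genes. In 9193 genes (55.0%) the ANKO and WT libraries did not overlap at all, against 2.86% by chance. ANKO libraries also carried more skeletal muscle RNA, described with the cell type markers, and a lower share of mitochondrial transcripts outside rRNA (2.21% to 3.08% against 6.90% to 7.32%). Genes that are not protein-coding held 3.74% to 5.93% of the counts in ANKO and 3.09% to 3.32% in WT. With the muscle marker level as a covariate the number of called genes was 3899, of which 2250 were higher and 1649 lower. The covariate followed genotype (Pearson r = 0.845 over the 8 libraries), and the median standard error of a gene rose from 0.18 to 0.29.

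The genes that define brown fat fell in ANKO. Ucp1, the uncoupling protein of the inner mitochondrial membrane that makes heat, dropped 5.39-fold, from 5949 ± 2602 to 1103 ± 631 CPM (SD, n = 4 each; log2 fold change -2.43, standard error 0.52, edgeR adjusted p = 0.00296). Dio2, which converts thyroxine to active thyroid hormone, dropped 9.86-fold. Ppargc1a, a coactivator of mitochondrial genes, dropped 4.25-fold, and its relative Ppargc1b dropped 3.20-fold. Slc27a2, a very long-chain acyl-CoA synthetase, had the largest decrease of the list, 13.01-fold, and the lipid droplet gene Cidea dropped 2.64-fold. Of 26 thermogenic genes tested, 20 were lower and 1 higher, with a median log2 fold change of -1.37 (camera adjusted p = 2.33e-05). The list was not called with an estimated correlation (adjusted p = 0.388). The 1 higher member was Fgf21, a secreted factor, at 2.57 CPM in ANKO and 0.378 CPM in WT. Elovl3, Zic1, Lhx8, Acot2 and Bmp8b did not pass the test, with log2 fold changes of 0.39, 0.08, 0.37, -0.34 and -0.21. Adjusted over the list alone, 20 were lower and 2 higher. With the muscle marker level as a covariate Ucp1, Ppargc1a, Dio2 and Cidea were no longer called. Their log2 fold changes went to -1.15 ± 0.75, -1.12 ± 0.58, -1.20 ± 0.55 and -1.41 ± 0.54 (standard errors), from -2.43 ± 0.52, -2.09 ± 0.40, -3.30 ± 0.56 and -1.40 ± 0.31. Slc27a2 kept its call at -2.94 ± 0.31, from -3.70 ± 0.27. Without WT3 and WT4 Ucp1, Ppargc1a and Dio2 stayed called at -1.79, -1.497 and -2.04.

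Adipocyte genes in general fell as well. Of 19 general adipocyte markers 16 were lower and 0 higher, with a median log2 fold change of -0.88 (camera adjusted p = 2.18e-06, and adjusted p = 0.380 with an estimated correlation). Cfd, which encodes the serine protease adipsin, dropped 10.6-fold from 3551 ± 713 to 336 ± 78.4 CPM. Acvr1c, an activin receptor, dropped 3.598-fold. Pparg, the master regulator of adipocyte differentiation, dropped 2.10-fold (edgeR adjusted p = 0.000164), and Adipoq, which encodes adiponectin, dropped 1.84-fold. The β-adrenergic and lipolysis list had 19 of 24 members lower and 1 higher (median -1.06, camera adjusted p = 8.20e-06, and adjusted p = 0.380 with an estimated correlation). Gnas, the stimulatory G protein subunit, dropped 3.91-fold and the phosphodiesterase Pde4d 3.20-fold. The triglyceride lipase Pnpla2 dropped 2.22-fold, the hormone-sensitive lipase Lipe 1.55-fold and the β3-adrenergic receptor Adrb3 1.53-fold. Pde4b was the 1 higher member. White adipocyte markers went the other way, with 8 of 10 higher and 1 lower (median log2 fold change 1.41, camera adjusted p = 0.0152, and adjusted p = 0.382 with an estimated correlation). The members with the smallest p were Trim14, also known as an adaptor of antiviral signalling, up 7.90-fold, and the amino acid transporter Slc7a10, up 2.15-fold. The resistin gene Retn was the 1 lower member. Hoxc9, Hoxc10 and Tcf21 of this list had too few counts to be tested. Among the higher members Wfdc21 and Agt were low, at 0.381 and 1.28 CPM in WT and 2.07 and 4.55 CPM in ANKO. With the muscle marker level as a covariate the white adipocyte list was no longer called (median 1.14, adjusted p = 0.141), nor was it without WT3 and WT4 (median 1.34, adjusted p = 0.0610), and Adipoq, Lipe, Pnpla2 and Adrb3 lost their calls with the covariate. Their log2 fold changes stayed at -0.73 ± 0.26, -0.67 ± 0.31, -0.96 ± 0.31 and -0.51 ± 0.35 (standard errors), from -0.88 ± 0.14, -0.63 ± 0.17, -1.15 ± 0.17 and -0.61 ± 0.18, so the wider errors ended these calls. Of the 8 caveolar genes 2 were higher (Cavin3, 3.32-fold, and Pacsin3, 2.15-fold) and 1 lower (Cav1, 1.53-fold). That list was not called (camera adjusted p = 0.850, and adjusted p = 0.901 with an estimated correlation), and Cav1 lost its call with the muscle covariate (log2 fold change -0.10 ± 0.25, from -0.61 ± 0.16) and without WT3 and WT4 (-0.41).

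Mitochondrial genes were lower among the nuclear genes and the tested genes of the mitochondrial genome. Of the nuclear subunits, 35 of 36 in complex I, 14 of 14 in complexes II and III, and 14 of 14 in complex IV were lower, with median log2 fold changes of -1.09, -1.16 and -1.07 (camera adjusted p = 5.33e-09, 3.47e-05 and 5.99e-05). None of the 3 lists was called with an estimated correlation (adjusted p = 0.388 for each), and adjusted over the list alone 36 of 36 complex I genes were lower. Examples are Ndufs7 (2.55-fold lower), Ndufb3 (2.37-fold), Uqcrb (2.02-fold), Uqcr11 (2.47-fold), Cox6c (2.66-fold) and Cox7c (2.10-fold). In ATP synthase 11 of 16 members were lower and 2 higher (median -0.89, camera adjusted p = 0.0132, and adjusted p = 0.526 with an estimated correlation). Atp5h dropped 2.38-fold and Atp5e 2.21-fold. The 2 higher members had low counts for this list: Atp5g1 (1.12 CPM in WT, 5.67 in ANKO) and the inhibitor Atpif1 (5.86 and 13.2 CPM). Of the 8 mitochondrially encoded genes tested 7 were lower (median -1.75, camera adjusted p = 5.98e-05, and adjusted p = 0.380 with an estimated correlation), among them mt-Nd6 (3.89-fold) and mt-Nd4 (3.54-fold). The other 5 of the 13 (mt-Nd4l, mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8) had too few counts to be tested, while mt-Co1 was at 45657 CPM in WT. mt-Nd3, the 1 tested gene that was not called, was also low, at 0.902 CPM in WT and 0.534 CPM in ANKO. Whether these low counts come from the levels or from the way reads were assigned cannot be told. In the TCA cycle 17 of 20 genes were lower, with Sucla2 down 3.45-fold and Suclg2 down 2.66-fold (median -1.27, camera adjusted p = 3.57e-06, and adjusted p = 0.388 with an estimated correlation). In fatty acid oxidation 26 of 29 were lower and 1 higher (median -1.53, camera adjusted p = 1.30e-08, and adjusted p = 0.382 with an estimated correlation). Etfa, an electron transfer flavoprotein subunit, dropped 3.96-fold. The 1 higher member was Cpt1a, the carnitine palmitoyltransferase of liver type, which rose from 16.8 to 61.4 CPM while the muscle type Cpt1b fell.

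Genes that maintain mitochondria moved the same way. Of 19 genes of mitochondrial DNA maintenance and dynamics 16 were lower (median -0.64, camera adjusted p = 5.98e-05, and adjusted p = 0.380 with an estimated correlation), including the exonuclease Mgme1 (2.18-fold) and the mitofusin Mfn1 (1.81-fold). Adjusted over the list alone 16 were lower and 1 higher. Of 14 mitochondrial chaperones and proteases 11 were lower, with Hspe1 down 2.82-fold and Trap1 down 2.18-fold (median -1.07, camera adjusted p = 0.000496, and adjusted p = 0.388 with an estimated correlation). With the muscle marker level as a covariate the ATP synthase list was no longer called (median -0.64, adjusted p = 0.136), and among the genes named here Uqcr11, Cox7c and Atp5e lost their calls, at -0.97 ± 0.35, -0.61 ± 0.26 and -0.85 ± 0.29 from -1.30 ± 0.21, -1.07 ± 0.18 and -1.15 ± 0.17. Hspe1 kept its call at a log2 fold change of -0.873, from -1.495.

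Other genes of NAD+ metabolism moved in both directions. Of 15 genes of NAD+ synthesis and salvage besides Nampt, 4 were higher and 6 lower. The 4 higher members had low WT means, of 0.456 to 9.01 CPM. They were Nmnat2 and Qprt (1.14 and 1.52 CPM in ANKO), and Nmrk2 and Nnt, which the closing section takes up. The 6 lower members had WT means of 36.3 to 761 CPM. The median log2 fold change was -0.27, the mean was 0.16 and the list was not called (camera adjusted p = 0.413, and adjusted p = 0.714 with an estimated correlation). The mitochondrial NAD kinase Nadk2 dropped 2.14-fold and the mitochondrial NAD+ carrier Slc25a51 2.88-fold. Adjusted over the list alone 5 were higher and 7 lower. Of 24 NAD+-consuming enzymes 10 were higher and 6 lower (median 0.15, camera adjusted p = 0.480, and adjusted p = 0.714 with an estimated correlation). Parp8 rose 4.53-fold and Parp11 2.98-fold, both of the PARP family, while the deacetylase Sirt1 dropped 1.58-fold from 44.7 ± 2.21 to 28.3 ± 1.07 CPM (SD, n = 4 each). Slc25a51 lost its call with the muscle covariate, where its log2 fold change went from -1.53 ± 0.23 to -0.81 ± 0.32.

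Genes of lipid and sugar metabolism showed no common direction. In fatty acid and triglyceride synthesis 11 of 24 genes were higher and 4 lower (median 0.64, camera adjusted p = 0.600, and adjusted p = 0.901 with an estimated correlation). The mitochondrial citrate carrier Slc25a1 rose 4.01-fold and the malic enzyme Me1 4.09-fold. The 4 lower members were Acacb, Gpam, Dgat1 and Dgat2, with log2 fold changes of -0.75, -1.64, -0.69 and -1.58. In cholesterol synthesis 8 of 22 were higher and 3 lower (median 0.44, camera adjusted p = 0.330, and adjusted p = 0.849 with an estimated correlation), with the squalene epoxidase Sqle up 3.33-fold. In glycolysis 8 of 20 were higher and 4 lower (median 0.15, camera adjusted p = 0.701, and adjusted p = 0.901 with an estimated correlation), or 8 and 5 adjusted over the list alone. Hk1 rose 2.27-fold and the lactate transporter Slc16a3 3.52-fold. In creatine and calcium cycling 5 of 9 were higher and 2 lower (median 0.54, camera adjusted p = 0.369, and adjusted p = 0.439 with an estimated correlation), with Gatm up 2.30-fold and Ckmt1 at 1.13 CPM in ANKO against 0.142 CPM in WT. Slc25a1, Me1, Sqle, Gatm and Ckmt1 lost their calls with the muscle covariate. The log2 fold changes of the first 3 and of Ckmt1 stayed at 1.66 ± 0.67, 1.67 ± 0.67, 1.58 ± 0.63 and 2.84 ± 1.18 (from 2.003 ± 0.36, 2.03 ± 0.36, 1.74 ± 0.32 and 2.93 ± 0.56), and that of Gatm went from 1.201 ± 0.17 to 0.71 ± 0.28. In the circadian clock list 5 of 19 were higher and 5 lower (median -0.32, camera adjusted p = 0.721, and adjusted p = 0.901 with an estimated correlation), with the transcription factors Hlf and Tef down 2.39-fold and 1.69-fold. Tef lost its call with the muscle covariate, at -0.43 ± 0.19 from -0.76 ± 0.12.

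Macrophage, lymphocyte and interferon-response genes were much higher in ANKO. Of 20 macrophage markers 19 were higher, with a median log2 fold change of 3.30 (camera adjusted p = 2.83e-11, and adjusted p = 0.232 with an estimated correlation). Mpeg1, a pore-forming protein of phagocytes, rose 20.998-fold from 11.2 ± 0.63 to 234 ± 46.7 CPM (SD, n = 4 each; edgeR adjusted p = 1.04e-07). Adgre1, the F4/80 antigen, rose 9.97-fold. Cd163 was the 1 marker that did not pass, at 19.6 CPM in WT and 18.1 CPM in ANKO. All 25 interferon-stimulated genes were higher (median 3.06, camera adjusted p = 8.21e-14, and adjusted p = 0.232 with an estimated correlation), with the smallest p for the transcription factor Irf7 (17.3-fold) and the ISG15 protease Usp18 (11.4-fold). Of 18 cytokine and chemokine genes 17 were higher (median 3.398, camera adjusted p = 6.12e-08, and adjusted p = 0.0694 with an estimated correlation), with Ccl5 at 7.94 CPM in ANKO against 0.363 CPM in WT and Cxcl16 up 4.61-fold. Of 17 lymphocyte markers 16 were higher (median 3.28, camera adjusted p = 8.47e-08, and adjusted p = 0.232 with an estimated correlation), including the T cell kinase Lck (9.95-fold) and Nkg7 (14.9-fold). Of 14 neutrophil and mast cell markers only 6 had enough counts to be tested, which left out S100a8, S100a9, Retnlg, Cxcr2, Ngp, Camp, Ly6g and Ms4a2. Of the 6 tested 5 were higher (median 1.39, camera adjusted p = 0.0140, and adjusted p = 0.380 with an estimated correlation). Csf3r, the granulocyte colony-stimulating factor receptor, rose 9.74-fold and the mast cell protease Mcpt4 2.75-fold. With the muscle covariate the neutrophil and mast cell list was no longer called (median 0.83, adjusted p = 0.0915), nor was Mcpt4 (1.05 ± 0.43, from 1.46 ± 0.23).

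The largest rises were those of Mmp12, Atp6v0d2, Dmrtc1a, Gpnmb, Apol9a, Trem2, Slfn4 and Clec4d. Mmp12, the macrophage elastase, went from 0.639 ± 0.267 to 181 ± 116 CPM (SD, n = 4 each; log2 fold change 8.21, standard error 0.70, edgeR adjusted p = 3.76e-05). Atp6v0d2, a proton pump subunit, went from 0.372 to 59.0 CPM. Gpnmb, a glycoprotein of lipid-laden macrophages, rose from 3.36 to 445 CPM and the lipid receptor Trem2 from 0.567 to 52.4 CPM, and both are also members of the macrophage list. Slfn4 rose from 0.250 to 22.8 CPM and Clec4d from 0.0990 to 9.93 CPM. Dmrtc1a and Apol9a had 4 counts each over the 4 WT libraries and 305 and 254 counts in ANKO, and without WT3 and WT4 their log2 fold changes were 6.17 and 6.04 (from 7.08 and 6.95). Dmrtc1a, Apol9a and Slfn4 have close relatives in the genome, so their counts are uncertain where reads are shared. The largest falls were those of Cyp2b10, Sgk2, Mmd2, Pon1, Tectb, Gmpr, Syt14 and Slc27a2. Cyp2b10, a xenobiotic-metabolising cytochrome P450, dropped from 53.1 ± 44.5 to 0.399 ± 0.129 CPM (SD, n = 4 each; log2 fold change -7.10, standard error 1.09, edgeR adjusted p = 0.00109). The kinase gene Sgk2 dropped 61.4-fold, Mmd2 46.6-fold, the paraoxonase Pon1 32.0-fold, Tectb 17.4-fold, the GMP reductase Gmpr 17.1-fold and Syt14 14.5-fold. With the muscle marker level as a covariate Tectb lost its call (-2.06 ± 0.68, from -4.12 ± 0.72), and Cyp2b10, Mmd2 and Gmpr kept theirs at log2 fold changes of -4.07, -3.02 and -1.87 (from -7.10, -5.54 and -4.10). Sgk2 kept its call at -4.37 (from -5.94). The named rises all stayed called. Mmp12, Apol9a, Slfn4 and Trem2 went to 6.49, 5.11, 5.44 and 5.52 (from 8.21, 6.95, 6.56 and 6.60). Gpnmb and Atp6v0d2 went to 6.07 and 6.45 (from 7.07 and 7.36), and Dmrtc1a and Clec4d to 7.63 and 7.01 (from 7.08 and 6.47). Single libraries also moved these folds: Mmd2 was at 12.56 CPM in ANKO2 and its log2 fold change was -6.31 without it, and without ANKO3 that of Sgk2, which rests on 18 counts in ANKO, was -6.82 and that of Tectb -4.87. Without WT3 and WT4 Cyp2b10, Sgk2, Mmd2, Tectb and Gmpr were at -5.25, -4.97, -4.03, -2.93 and -2.76, all still called.

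**Figure D2:**
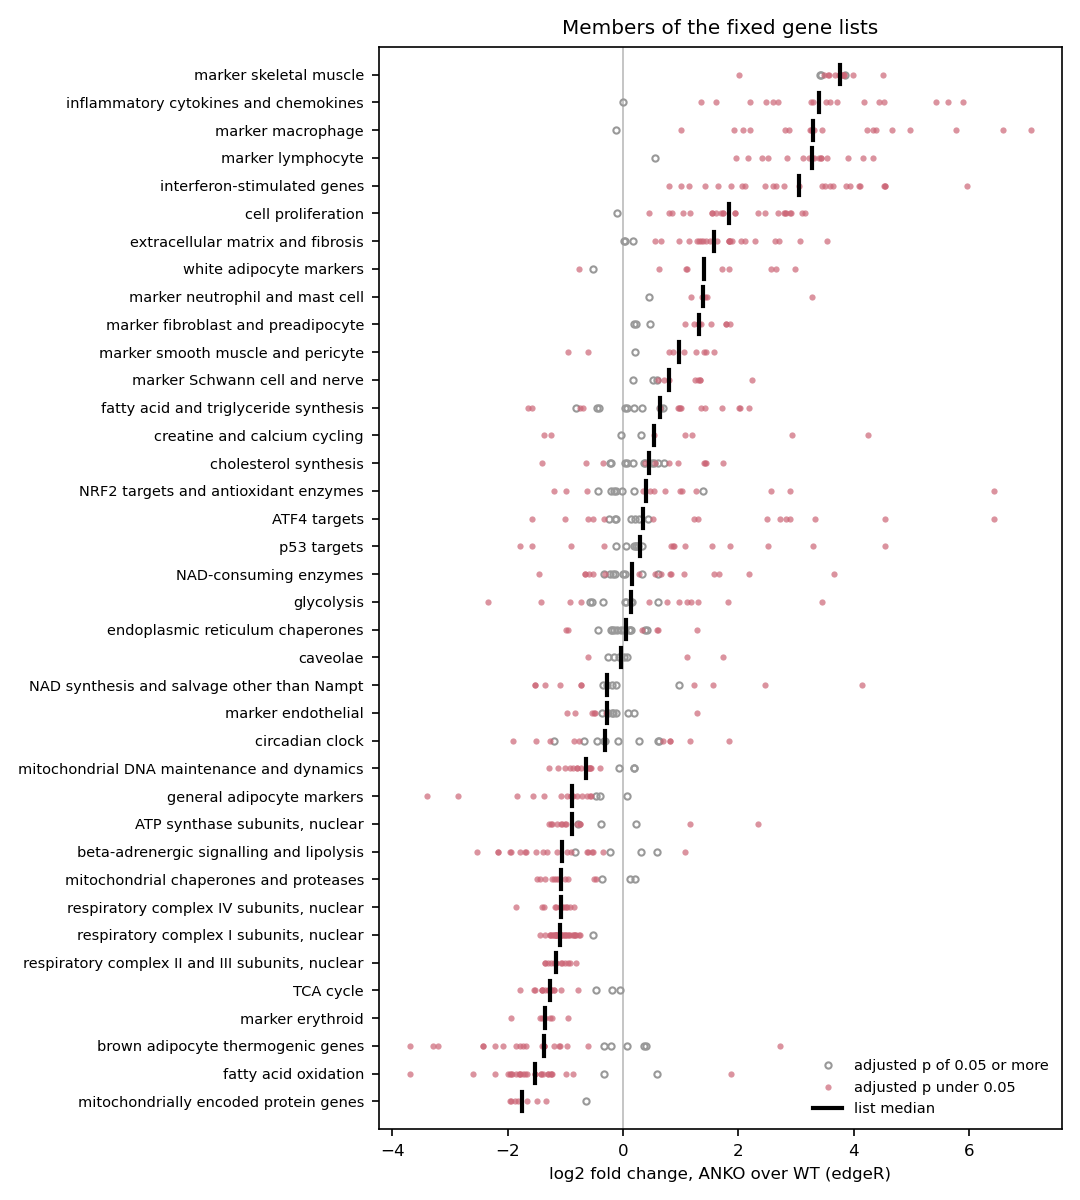
Log2 fold changes (ANKO over WT, edgeR) of the tested members of the 38 lists fixed before the data were examined, ordered by list median. Filled points have an adjusted p under 0.05, open points do not, and black bars are list medians, from -1.75 for the mitochondrially encoded genes to 3.76 for the skeletal muscle markers.

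Matrix and proliferation genes were also higher. Of 26 matrix and fibrosis genes 23 were higher (median 1.57, camera adjusted p = 1.68e-08, and adjusted p = 0.380 with an estimated correlation). The membrane metalloproteinase Mmp14 rose 6.53-fold and the proteoglycan Bgn 3.71-fold, while Col4a1, Col4a2 and Loxl1 did not pass, with log2 fold changes of 0.03, 0.01 and 0.18. Of 24 proliferation genes 23 were higher (median 1.84, camera adjusted p = 1.69e-07, and adjusted p = 0.380 with an estimated correlation), with the replication helicase subunit Mcm6 up 2.93-fold and Aurkb up 6.44-fold. Stress-response lists were split. Of 22 ATF4 targets 10 were higher and 5 lower (median 0.35, mean 1.13, camera adjusted p = 0.122, and adjusted p = 0.388 with an estimated correlation). The mitochondrial folate enzyme Mthfd2 rose 7.42-fold and the serine synthesis enzyme Psat1 5.67-fold. Of 20 NRF2 targets and antioxidant enzymes 10 were higher and 3 lower (median 0.41, camera adjusted p = 0.142, and adjusted p = 0.594 with an estimated correlation), or 10 and 4 adjusted over the list alone. Nqo1 rose 5.92-fold, and the cystine transporter Slc7a11 went from 0.187 to 15.8 CPM. With the muscle marker level as a covariate the ATF4 and NRF2 lists were called (adjusted p = 0.0102 and 0.0101). Of 20 p53 targets 9 were higher and 4 lower (median 0.29, camera adjusted p = 0.111, and adjusted p = 0.380 with an estimated correlation), or 11 and 4 adjusted over the list alone, with Pmaip1 up 9.84-fold and Zmat3 up 1.82-fold. Of 18 endoplasmic reticulum chaperones 4 were higher and 2 lower (median 0.05, camera adjusted p = 0.931, and adjusted p = 0.974 with an estimated correlation). Sdf2l1 rose 2.44-fold and Pdia4 1.53-fold, and Pdia4 lost its call with the muscle covariate while its log2 fold change stayed at 0.59 ± 0.20, from 0.61 ± 0.11.

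Markers of other cell types did not move together. Skeletal muscle markers rose most, with 13 of 16 higher and a median log2 fold change of 3.76 (camera adjusted p = 0.000166, and adjusted p = 0.439 with an estimated correlation), or 15 of 16 adjusted over the list alone. Their mean log2 CPM was 8.34 to 8.92 in the ANKO libraries and 5.12, 6.51, 2.31 and 1.02 in WT1 to WT4, so the WT libraries differed widely. Myl1, a myosin light chain, rose 4.04-fold, and Tnnc2 had 86 counts in ANKO against 8 in WT. Fibroblast and preadipocyte markers were higher in 9 of 12 cases (median 1.31, camera adjusted p = 6.23e-05, and adjusted p = 0.112 with an estimated correlation), with Dpt up 2.89-fold and Cd34 up 2.11-fold. Of 10 smooth muscle and pericyte markers 7 were higher and 2 lower (median 0.96, camera adjusted p = 0.0356, and adjusted p = 0.382 with an estimated correlation). Des, which skeletal muscle also expresses, rose 2.98-fold and Lmod1 2.70-fold, whereas the pericyte genes Rgs5 and Cspg4 fell. Of 11 Schwann cell and nerve markers 8 were higher (median 0.79, camera adjusted p = 0.00649, and adjusted p = 0.388 with an estimated correlation), or 9 adjusted over the list alone, with Scn7a up 2.46-fold and Ncam1 up 2.36-fold. Of 14 endothelial markers 6 were lower and 1 higher (median -0.29, camera adjusted p = 0.0465, and adjusted p = 0.388 with an estimated correlation). The receptors Kdr and Flt1 dropped 1.96-fold and 1.78-fold, and Vwf was the 1 higher member. All 7 erythroid markers were lower (median -1.35, camera adjusted p = 0.00441, and adjusted p = 0.382 with an estimated correlation), including Hba-a2 (2.36-fold, a near-identical copy of Hba-a1) and Epb42 (3.86-fold). The endothelial list lost its call under several settings and the smooth muscle list under 3, as listed with the other settings. With the muscle covariate the erythroid list (median -0.48, adjusted p = 0.0523) and Tnnc2, Ncam1, Flt1 and Hba-a2 were no longer called. Their log2 fold changes were 1.72 ± 1.09, 1.19 ± 0.39, -0.45 ± 0.15 and -0.40 ± 0.31, from 4.50 ± 0.59, 1.24 ± 0.20, -0.83 ± 0.11 and -1.24 ± 0.24, and the log2 fold change of Myl1 went from 2.02 to 0.94.

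**Figure D3:**
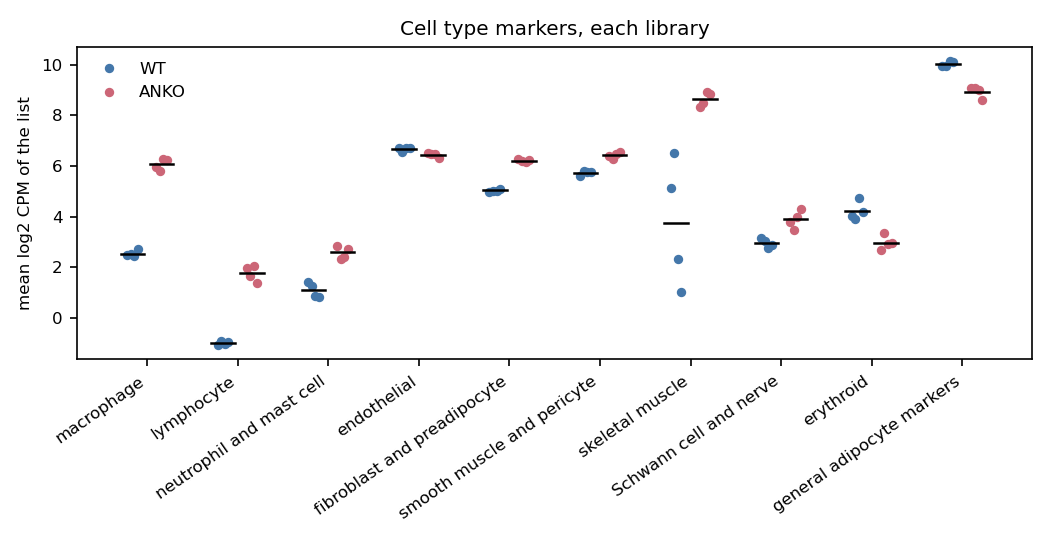
Mean log2 CPM of each cell type marker list and of the general adipocyte markers, per library (WT blue, ANKO red), with bars at the group means of 4. Macrophage markers lie at 5.79 to 6.28 in ANKO and 2.46 to 2.71 in WT, and the skeletal muscle markers spread from 1.02 to 6.51 within WT.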

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

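Of the tests in this part, those on the unequal size of the thermogenic falls and on the genes beside Adipoq were chosen after the result was seen. The tests of thinning, of the muscle covariate and of list differences were written before their values were computed, but after single genes (Acta1, Ckm, Ucp1, Adipoq and the genes with the smallest p, many of macrophages) had been looked at. The covariate tests ask the value to clear its pre-set bound by 1 median standard error, a margin added afterwards. With 2 the thermogenic value would not clear its bound.

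Grouping by genotype stood apart from other groupings. Of the 35 splits of the 8 libraries into 4 and 4, 1 (the real one) gave as many as 9726 called genes, and the highest of the others gave 0. Every other split mixes the genotypes, so the genotype difference widens its within-group spread and few calls could arise. The gene count therefore does not decide on chance, nor can it tell genotype from anything else the ANKO mice share. For the number of called lists, 4 of the 35 splits gave as many as the real 26 and the highest other gave 26, so chance cannot be excluded by this test. The other 3 each exchange ANKO2 with 1 WT library and so keep most of the genotype contrast. Splits with a pair of each genotype on either side still called up to 17 lists (WT1 and WT2 with ANKO3 and ANKO4), so the list calls with the preset correlation are weaker evidence than their p-values.

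Skeletal muscle transcripts were higher in ANKO, and WT1 and WT2 held more of them than WT3 and WT4. Acta1 was at 1811 to 2663 CPM in ANKO and at 141, 457, 16.1 and 4.41 CPM in WT1 to WT4. The median log2 fold change of the markers was 3.791 after thinning, against 3.76 before. Random thinning keeps the expected proportions of genes, so it bears only on losses at low counts. Other traits of the shallow libraries were not tested. The 16 markers kept nearly 1 set of proportions: the log2 ratio of the ANKO excess to that of WT2 had a median of 2.27 and an SD of 0.3144 over markers, in line with muscle tissue in the dissected fat. Whether more muscle came with the fat by dissection or for a reason tied to genotype stays open and was not tested.

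Macrophage and interferon genes were higher in ANKO. The values that follow are for the macrophage markers alone, so they do not cover the interferon genes. The macrophage median was 3.342 after thinning (3.30 before), which bears only on losses at low counts. A lower share of adipocytes alone is argued against because the macrophage and endothelial medians lay 3.585 apart on the log2 scale. Cells carried in with muscle are argued against by the WT libraries. The mean log2 CPM of the muscle markers was 5.12, 6.51, 2.31 and 1.02 in WT1 to WT4. That of the macrophage markers was 2.47, 2.51, 2.46 and 2.71. With the muscle covariate, which follows genotype, the macrophage median was 3.491 (median standard error of a gene 0.34). A change in the immune cells of ANKO brown fat, in number or in state, is a hypothesis that stays open.

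Thermogenic genes were lower in ANKO. The list median was -1.338 after thinning (-1.37 before), which bears only on losses at low counts. With the muscle covariate it was -1.142 (median standard error of a gene 0.44), beyond the pre-set bound of -0.5. The covariate is a mean of log2 levels and follows genotype (Pearson r = 0.845). It does not measure the share of muscle RNA, so muscle tissue as the whole cause stays open. For Ucp1, Dio2 and Ppargc1a it stays open as well, since their calls ended. Their log2 fold changes shrank from -2.43 ± 0.52, -3.30 ± 0.56 and -2.09 ± 0.40 to -1.15 ± 0.75, -1.20 ± 0.55 and -1.12 ± 0.58. In WT1 to WT4, Ucp1 was at 3369, 4170, 8829 and 7430 CPM, but Adipoq at 987, 1117, 1169 and 1182 CPM. Dilution by muscle RNA would lower adipocyte transcripts alike, so the shrinkage of these 3 genes does not measure dilution. The list mean fell by 0.2343 more than that of the general adipocyte markers, a gap inside the pre-set bound of 0.3 that the libraries did not resolve (exact two-sided permutation p = 0.257), so a lower share of adipocyte RNA stays open for the list as a whole. A test devised after that outcome decides nothing: 61.54% of the 26 genes lay more than 2 standard errors from the adipocyte marker median, but so did 7 of the 19 adipocyte markers themselves.

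Among 282 groups of 4 libraries examined for a far sample, 18 had one, where chance gives about 1 in 20. In WT, Nampt in WT3 was at 571.3 CPM against 484 to 495 CPM in the others. Ppargc1b in WT1 was at 188.4 CPM (others 160 to 163) and Sqle in WT1 at 18.42 CPM (others 11.02 to 11.65). Adgre1 in WT4 was at 11.72 CPM (others 9.49 to 9.60). In WT2 the mean log2 CPM of the p53 targets was 4.128 and that of the endothelial markers 6.543, both the lowest of their group. In ANKO4 the lowest values were those of Pparg (154.6 CPM), Pde4d (93.83 CPM), Ndufs7 (96.89 CPM) and mt-Nd4 (747.2 CPM). ANKO4, the shallowest library, also had the lowest list means of the general adipocyte markers (8.588), of β-adrenergic signalling and lipolysis (6.463) and of the mitochondrially encoded genes (8.875). In ANKO2, Mmd2 was highest at 12.56 CPM, while Mmp14 (56.47 CPM) and Scn7a (165.7 CPM) were lowest. Parp8 was lowest in ANKO3 at 16.08 CPM, and the ATF4 list mean was highest in ANKO1 at 4.747.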

How the results depend on the processing

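Thinning to the lowest library total and leaving out WT1 with WT2 or WT3 with WT4 were chosen after seeing the data. Nampt was lower and called under each setting run. The number of called genes was 9726, between 8942 and 10467 with 1 library left out, 7469 of 13528 tested after thinning, 10557 without WT1 and WT2 and 8283 without WT3 and WT4. The largest drop came with the muscle marker covariate: 3899 genes, 2250 higher and 1649 lower, and 5 of the 9 marker lists called. There 27 of the 102 named genes lost their call, each with the same sign. The covariate follows genotype and leaves 5 residual degrees of freedom in place of 6, which widens the errors. The skeletal muscle list then had a median of -0.094, since its own level is the covariate. Asking for a log2 fold change of at least 1 left 4786 genes, 1209 of them lower, by construction. Camera with an estimated correlation called 0 lists, so 0 higher, 0 lower and 0 marker lists, against 26, 12, 14 and 9; fry added 6 calls and lost 1 (ATP synthase, adjusted p = 0.0659). The endothelial list was not called with upper-quartile factors, the strict filter, thinning or the muscle covariate, without WT3 and WT4, or with WT3, ANKO2 or ANKO4 left out (adjusted p = 0.0512 to 0.191, medians -0.20 to -0.35). The smooth muscle list was not called with upper-quartile factors (adjusted p = 0.0504), without WT1 and WT2 (0.113) or without WT1 (0.0539), with medians of 0.90 to 1.06. Without WT3 and WT4 the NRF2 list was called (adjusted p = 0.0378). Of 10 tested genes near Adipoq, counting Adipoq itself, 3 were lower (Adipoq, the pseudogene Gm6493 and Eif4a2) and 0 higher. The number called was 5 with DESeq2, 6 with limma-voom, 0 with the muscle covariate, 5 without WT1 and WT2, 1 without WT3 and WT4, and 1 to 4 with 1 library left out (1 without WT3 and 1 without WT4). The cause was not tested.

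The replicate numbers were tried as a paired block, which called 9239 genes. Same-numbered libraries did not deviate together (correlations over genes of 0.11, -0.01, 0.07 and -0.05), so no pairing by number was seen, though it cannot be excluded. In WT, libraries 1 and 2 resembled each other, as did 3 and 4. Their log2 CPM correlated at 0.988 and 0.992, against 0.976 to 0.978 across these pairs. In ANKO the chi-square per degree of freedom was also lowest for these pairs (7.16 and 14.1). By correlation, however, ANKO3 was closer to ANKO1 (0.985) than to ANKO4 (0.975). What sets the pairs apart was not tested. No list or named gene changed its call with the block.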

Other observations

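The 7 lists in this paragraph were chosen after the values had been seen, as were the genes named from them. No p-value is given for them, since a test on the values that chose a list has no meaning. Genes of branched-chain amino acid breakdown were lower in ANKO in 17 of 18 cases (median log2 fold change -1.49). Bcat2, the mitochondrial aminotransferase, fell by 2.08 on the log2 scale, Dbt by 2.26 and Aldh6a1 by 2.21. Of 25 peroxisomal genes 19 were lower (median -0.75). Of 15 complement genes 14 were higher (median 2.88). C4b went from 14.5 ± 3.32 to 315 ± 48.8 CPM (SD, n = 4 each), while C3 was the 1 lower member, from 1474 to 920 CPM. The list leaves out Cfd, complement factor D, named above among the adipocyte markers, which fell from 3551 to 336 CPM. All 16 antigen presentation genes were higher (median 1.86). Of 23 lysosomal genes 15 were higher and 1 lower (median 0.70). The protease Ctss rose from 10.1 to 371 CPM. Of 19 genes of lytic and programmed cell death 14 were higher (median 1.53). Among them the inflammatory caspases Casp1 and Casp4 rose by 3.41 and 3.503 on the log2 scale and the necroptosis effector Mlkl by 1.92. Macrophage, lymphocyte and interferon lists rose too (medians 3.30, 3.28 and 3.06), and Zbp1 and Nlrp3 also sit in the interferon and cytokine lists. The rise of the cell death genes can therefore not be told apart from more immune-cell RNA. Of 10 brown fat secreted factors and receptors 2 were higher and 6 lower (median -0.50). The receptor Erbb4 dropped from 50.6 to 5.36 CPM and its ligand Nrg4 from 281 to 94.1 CPM.

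The genes in this paragraph were also chosen after their values were seen. Scd1, a fatty acid desaturase, had the most counts of any gene in each ANKO library, and mt-Co1 in each WT library. Scd1 rose from 22349 ± 9626 to 56964 ± 19290 CPM (SD, n = 4 each; edgeR adjusted p = 0.01003). Fasn rose from 16317 ± 6532 to 32182 ± 11560 CPM and Acly from 1625 ± 991 to 5341 ± 2697 CPM. For each of the 3, WT1 lay above ANKO4 (Scd1 36485 and 31444 CPM, Fasn 24289 and 17707 CPM, Acly 2794 and 2107 CPM), and the fatty acid and triglyceride synthesis list was not called (camera adjusted p = 0.600). The leptin gene Lep rose from 21.7 ± 18.6 to 135 ± 22.1 CPM (46.4, 24.98, 4.12 and 11.2 CPM in WT1 to WT4), so its fold depends on the WT libraries kept. Nnt, the mitochondrial transhydrogenase in which C57BL/6J mice carry a deletion, was at 7.57, 15.7, 8.15 and 4.57 CPM in WT1 to WT4 and at 86.4, 29.4, 51.7 and 27.1 CPM in ANKO1 to ANKO4 (edgeR adjusted p = 0.00345). Nmrk2, a nicotinamide riboside kinase of muscle, was at 0.456 CPM in WT and 7.30 CPM in ANKO, in libraries that also held more muscle RNA. All 8 mice carry the C57BL/6J label, and whether the groups were littermates or shared a substrain is not given in the sources used here.

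A hypothesis tested after the values were seen was that the adiponectin Cre transgene may carry extra copies of genes beside Adipoq. The 9 other tested genes within 250 kb had a median log2 fold change of -0.102 with quartiles of -0.72 and 0.47, so members went both ways and the test decides nothing.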
